A study of Mus musculus with 8 samples.

How the data were processed

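Dorsal forebrain of male mouse embryos at embryonic day 12.5 was profiled by RNA sequencing in 4 Sufu-cKO and 4 control samples. RNA was extracted with a Qiagen RNeasy kit and libraries were made with an Illumina TruSeq stranded mRNA kit, per the labels' protocols. Such libraries mark the strand of the transcript and represent polyadenylated RNA. Reads were aligned with STAR 2.4.2a to the GRCm38 mouse genome, per the submitters' processing notes. The counting program, its strand setting, the annotation release and the program behind the deposited test are not given in the sources used here.

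The authors deposited raw counts per gene for the 8 samples, listed for 43629 Ensembl gene IDs, and these counts are the values tested here. A second deposited table gives a normalised signal per gene and sample, which the authors made by dividing each count by 1 size factor per sample. Those size factors equalled the median-of-ratios factors computed here from the counts. The same deposited table gives the authors' fold change, a ratio of Sufu-cKO to control, with a p-value and a false discovery rate per gene. The authors' log2 column was not used because spreadsheet error text stood among its numbers, and the log2 of the fold change column was taken instead. There, 1 gene ID had been turned into a spreadsheet formula and was restored from its own text. Gene symbols and coordinates are those of the authors' deposited table, on GRCm38. Of the tested gene IDs, 15284 were found in the GENCODE M21 annotation of the same build, and 15269 of them overlapped the deposited position.

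Groups were taken from the genotype labels, and the sample numbers from the titles. Neither says whether samples of a group came from separate embryos or litters, so p-values measure the spread between these samples, which may be technical. Total counts ranged from 27514357 to 34878838 per sample. Before samples were averaged, each pair within a group was compared by a chi-square test of counts, and every pair differed by far more than sampling noise, so each sample was counted once. Columns of values that matched no sample numbered 0.

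Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr at its defaults (a minimum count of 10 and a minimum total of 15), which left 15382 of the 25299 genes with any count. These genes held 99.94% of all counts. Libraries were scaled with TMM factors, and the genotypes were compared with edgeR's quasi-likelihood F-test with robust estimation, 2-sided, with Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. Levels are CPM, counts scaled to library size with TMM factors, as mean ± SD over the 4 samples of a group. Log2 fold changes are Sufu-cKO over control, with a standard error (SE) back-calculated from the log2 fold change and the F statistic of the test. For the mean of a gene list the SE was instead taken over its genes. Genes of a list vary together, so that SE understates the spread between samples. The biological coefficient of variation was 12.8%.

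A total of 31 gene lists was fixed before the data were examined, along with the test, the alternatives and the rule for named genes. Lists with at least 3 tested members were compared with all other genes by camera from limma 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. Benjamini-Hochberg adjustment ran over 30 lists, since the list of sex-linked genes served only as a check of the sex label. Beside camera with the preset value, camera with an estimated correlation and fry were run. The count of called members is given over all tested genes and adjusted over the list alone.

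The rule for named genes had 3 parts. It took the 10 largest rises and the 10 largest falls among called genes with a mean of at least 1 CPM and no overlap between the groups. It also took 15 genes chosen in advance, and up to 4 called members of each list with the smallest p, made up to 2 with the most abundant members. Gene models without a symbol of their own and pseudogenes were left out of the first part. List members named outside that rule were chosen after their values were seen, to complete a count. Some called genes that the rule names are not reported here, although the counts include them.

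Alternatives covered 3 other scalings, no low-count filter, a stricter filter of at least 1 CPM in 4 samples, DESeq2 1.42.0, limma-voom, edgeR without robust estimation, a test against a 1.2-fold change, 1 surrogate variable from sva 3.50.0, and each sample left out in turn. Covariates made from the GABAergic and choroid plexus lists were added after the data were seen. Called genes within 10 Mb of Emx1 and Sufu were compared with those elsewhere by Fisher's exact test. All 35 splits of the 8 samples into 4 and 4 were refitted.

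The gene test and the list test were tested on simulated data for this comparison. Counts were drawn for the 15382 tested genes at the mean levels, dispersions and library sizes of the real samples. In the gene simulation 15212 of them passed the filter. Of the genes changed 1.25-fold, 28% were recovered, against 66% at 1.5-fold, 70% at 2-fold and 94% at 4-fold. The fit made 137 calls there, 8 of them false, and 0 calls with no change simulated. A simulated list of 15 genes raised 1.5-fold among 30 lists was called by camera with the preset correlation (adjusted p = 5.06e-18) and with an estimated correlation (adjusted p = 0.00773). Each gene was drawn independently, whereas the real lists had estimated correlations as high as 0.81 (choroid plexus). The simulation therefore cannot show how the list test behaves on genes that vary together.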

Results

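Dorsal forebrain, the tissue that holds the primordium of the neocortex, was taken from male mouse embryos at E12.5 on a mixed background with C57BL/6J. The 8 samples fell into 2 genotypes with 4 samples each. The Sufu-cKO samples (Mut_295, Mut_317, Mut_337 and Mut_340) carried Emx1-cre and homozygous floxed Sufu alleles, so that cre recombinase, made in dorsal telencephalic progenitors and their descendants, removes the floxed part of Sufu there. The control samples (Cont_294, Cont_345, Cont_365 and Cont_370) had floxed Sufu on 1 or both chromosomes. SUFU is an intracellular inhibitor of Sonic hedgehog (SHH) signalling that binds the GLI transcription factors. Total counts per sample lay between 27514357 and 34878838. The comparison asked how loss of SUFU changes the specification of neocortical progenitors, and what becomes of SHH and FGF pathway genes.

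Sufu itself (ENSMUSG00000025231, chromosome 19, 46396896 to 46488804, GRCm38) fell from 112 ± 9.13 CPM in control to 40.6 ± 4.65 CPM in Sufu-cKO samples (SD, n = 4 each), and every Sufu-cKO sample lay below every control sample. The log2 fold change was -1.46 (SE 0.087, edgeR quasi-likelihood test, adjusted p = 1.07e-06). Genes that report active hedgehog signalling, an FGF ligand and transcription factors of more ventral progenitor domains stood among the largest rises. Of tested list members, 7 of 14 dorsal progenitor genes fell and 3 rose, and 7 of 12 WNT targets and 6 of 10 choroid plexus genes fell. In all, edgeR called 1689 of 15382 tested genes, with 822 higher and 867 lower in Sufu-cKO, and 431 of them differed at least 2-fold (204 higher and 227 lower). The groups did not overlap for 16.2% of tested genes, against 2.86% by chance, and for 1599 of the called genes. The first principal component, with 47.6% of the variance of the 500 most variable genes, separated the genotypes. Sufu counts are per gene and include exons outside the floxed part and cells without cre. Without Cont_345 the number of called genes was 1079, with 537 higher and 542 lower.

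**Figure D1:**
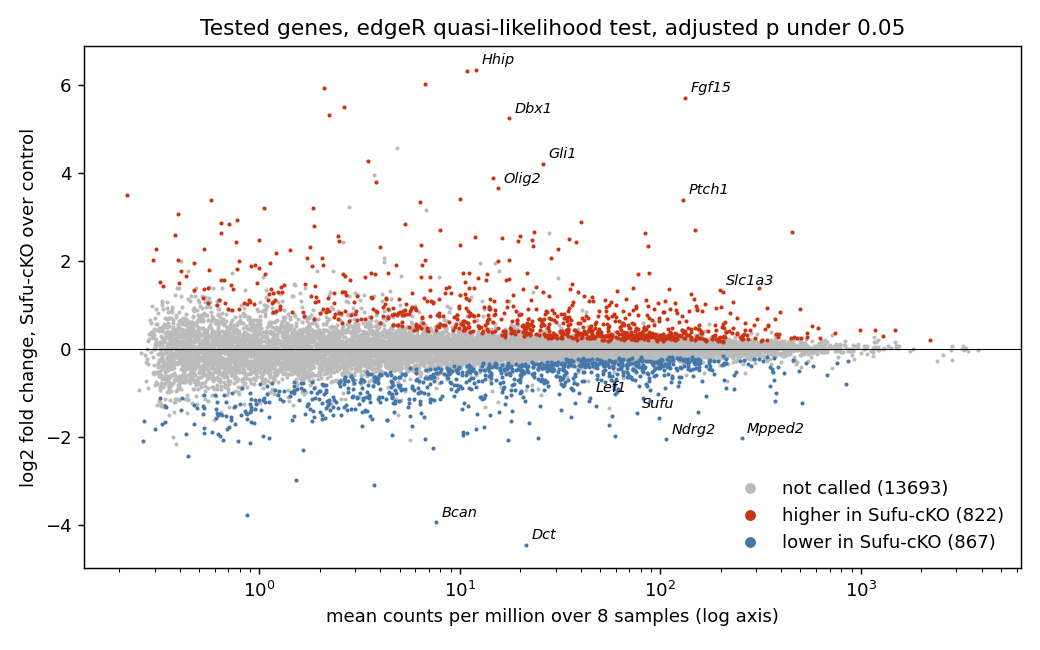
Log2 fold change of each tested gene (Sufu-cKO over control, n = 4 each) against its mean level in CPM on a log axis, with genes called by edgeR in color. Of the 1689 called genes, 822 lie above and 867 below the line at 0, and Hhip, Fgf15, Gli1 and Ptch1 stand far above the bulk of the genes at their level.

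Feedback genes of the hedgehog pathway rose strongly in all 4 Sufu-cKO samples. Gli1 (ENSMUSG00000025407, chromosome 10, 127329889 to 127341589), a transcription factor that is itself a direct target of the pathway, rose from 2.65 ± 0.993 to 49.5 ± 3.93 CPM (18.4-fold, n = 4 each; edgeR, adjusted p = 5.46e-06). Ptch1 (ENSMUSG00000021466, chromosome 13, 63508328 to 63573598), the SHH receptor, rose from 22.5 ± 3.88 to 237 ± 34.8 CPM (10.5-fold; edgeR, adjusted p = 8.48e-07). Hhip (ENSMUSG00000064325, chromosome 8, 79966115 to 80058006), which encodes a secreted antagonist that binds hedgehog ligands, went from 0.290 ± 0.094 to 23.8 ± 5.10 CPM, the largest rise among the named genes (log2 fold change 6.34, SE 0.231; edgeR, adjusted p = 3.45e-08).

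Of the 10 tested hedgehog targets, 6 rose, 2 fell and 2 did not pass the test, and adjusted over the list alone 6 rose and 3 fell. Smaller rises were seen for Ccnd1, which drives entry into the cell cycle (log2 fold change 0.84), and Bcl2, an inhibitor of apoptosis (0.57). The 2 targets that fell were Mycn (-0.66) and Sfrp1, a secreted WNT antagonist (-0.59). Camera placed the list above other genes (median log2 fold change 0.71, adjusted p = 0.00465), with adjusted p = 0.366 with an estimated correlation. Among 15 tested pathway components, Gli2 rose (log2 fold change 0.65), while Cdon (-1.23), Gas1 (-0.71) and Gpr161 (-0.18) fell. Cdon and Gas1 encode SHH co-receptors, and Gpr161 a receptor that restrains the pathway. The other 11 components did not pass, and 1 rose and 3 fell adjusted over the list alone. Gli3, the main GLI repressor of the dorsal telencephalon, had a log2 fold change of 0.08 (SE 0.070; edgeR, adjusted p = 0.581). The component list was not called by camera (adjusted p = 0.83), and its median (0.05) and mean (0.01) lay on the other side of 0 from the direction of the test. Transcripts of Shh numbered 0 to 1 counts per sample in both genotypes. Gpr161 kept its call without Mut_295 or Mut_340 and lost it without any other sample (edgeR, adjusted p from 0.0626 to 0.0823).

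Fgf15 (ENSMUSG00000031073, chromosome 7, 144896532 to 144900953), an FGF ligand of embryonic brain progenitors, rose from 4.96 ± 3.65 CPM in control to 261 ± 40.9 CPM in Sufu-cKO (n = 4 each). Its log2 fold change was 5.70 (SE 0.540; edgeR, adjusted p = 0.00119), and all 4 Sufu-cKO samples lay above all controls. Fgfbp3, which encodes a carrier protein for FGF ligands, rose 2.26-fold (edgeR, adjusted p = 0.000481). Fgfrl1, a receptor without a kinase domain, and Fgfr2 fell by 0.42 and 0.23 on the log2 scale. The other 10 of the 14 tested ligands and receptors did not pass, and adjusted over the list alone 2 rose and 3 fell. Fgf8 had too few reads to be tested, with 1 to 31 counts per control sample and 2 to 23 per Sufu-cKO sample.

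Of 16 tested genes listed in advance as feedback genes of FGF and MAPK signalling, Shisa2 (log2 fold change -0.46) and Phlda1 (-0.45) fell. Both also fell adjusted over the list alone, and the other 14 did not pass. Whether FGF signalling induces each listed gene in this tissue was not tested. Etv5 stood at -0.91 (SE 0.349) and Etv1 at 0.83 (SE 0.387), neither of them called, and Dusp6, Spry1, Spry2 and Spry4 lay between -0.14 and -0.01. Camera did not call the feedback list (median -0.14, adjusted p = 0.113) or the ligand and receptor list (adjusted p = 0.497). The feedback list passed, as lower, without Cont_365 (adjusted p = 0.0481) and without Mut_295 (adjusted p = 0.0339). Phlda1 kept its call only without Mut_295 (otherwise adjusted p from 0.0829 to 0.124 by edgeR), and Fgfr2 only without Cont_294 or Mut_337 (otherwise 0.0707 to 0.125).

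**Figure D2:**
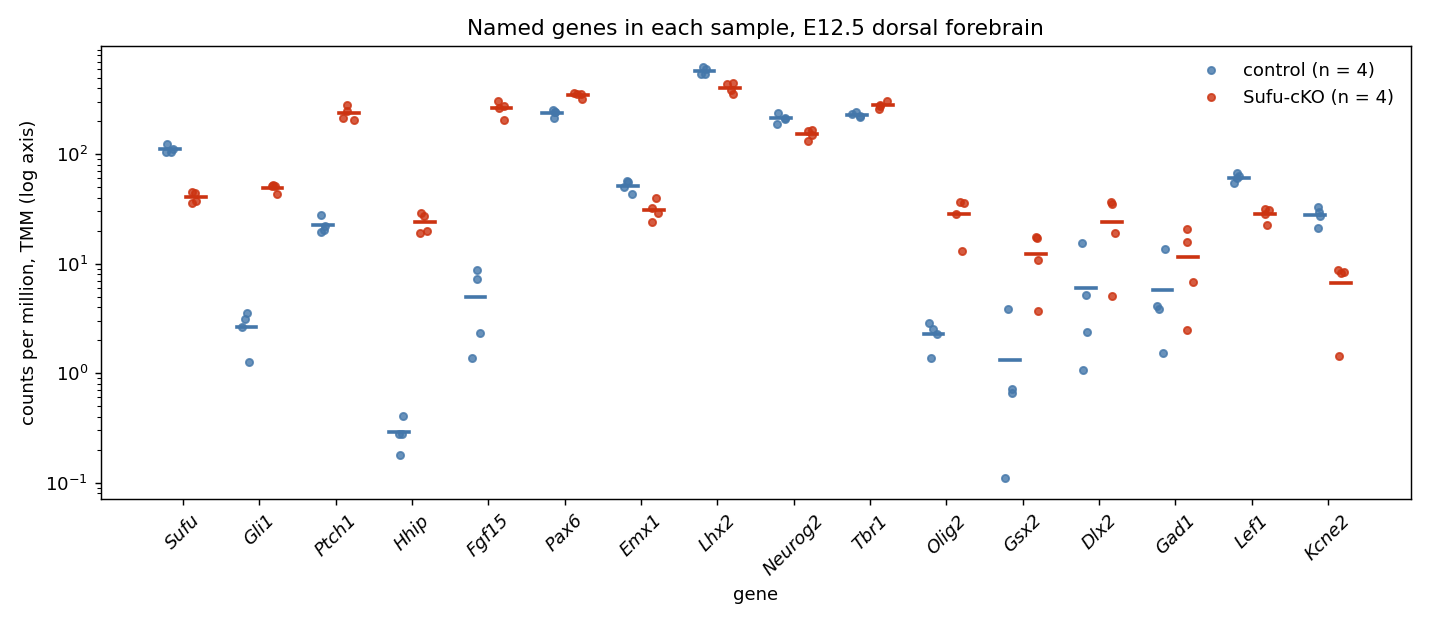
Level of 16 genes in each sample, in CPM with TMM factors on a log axis, with 4 control and 4 Sufu-cKO samples per gene as points and the mean of each group as a line. Gli1, Ptch1, Hhip, Fgf15 and Olig2 lie higher in every Sufu-cKO sample than in every control, Sufu, Emx1, Lhx2, Neurog2, Lef1 and Kcne2 lie lower, and the points of Gsx2, Dlx2 and Gad1 overlap between genotypes.

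Dorsal progenitor genes changed in both directions, with more falls than rises. Emx2 fell from 201 ± 19.6 to 122 ± 8.47 CPM (n = 4 each; edgeR, adjusted p = 8.41e-05), and Emx1, another homeobox gene of the pallium, fell from 51.6 ± 6.02 to 31.2 ± 6.50 CPM (edgeR, adjusted p = 0.00831). Emx1 also carries the cre allele in the Sufu-cKO samples. Lhx2, Dmrt3, Dmrta2, Neurog2 and Fezf2 fell as well, by 0.43 to 0.79 on the log2 scale. Pax6, by contrast, rose from 239 ± 17.9 to 347 ± 19.2 CPM (1.45-fold; edgeR, adjusted p = 0.000233), and Neurog1 (1.73-fold) and Tfap2c (log2 fold change 0.30) rose with it. In all 3 of the 14 tested members rose, 7 fell and 4 did not pass, and adjusted over the list alone 3 rose and 8 fell. Camera called the list lower (median -0.31, adjusted p = 0.0125), with adjusted p = 0.378 with an estimated correlation. Tfap2c kept its call only without Cont_345 or Mut_340 (otherwise adjusted p from 0.0525 to 0.103 by edgeR), and Fezf2 lost it without Cont_345, Cont_365 or Mut_340 (0.0625 to 0.0689).

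Of 14 tested markers of neural progenitors of any region, 6 rose, 2 fell and 6 did not pass. Slc1a3, the glial glutamate transporter of radial glia, went from 113 ± 8.16 to 286 ± 36.7 CPM (n = 4 each), Sox1 rose 2.18-fold, and Sox2, Vim, Nes and Pax6 rose by 0.43 to 0.58 on the log2 scale. The 2 members that fell were Sox3 (-0.74) and Id4 (-0.55). Adjusted over the list alone, 6 rose and 3 fell, and camera did not call the list (adjusted p = 0.113). The replication and mitosis list was called higher (22 tested, median 0.11, camera adjusted p = 0.000954; adjusted p = 0.366 with an estimated correlation), with Ccnb2, E2f1 and Ccne2 rising and 19 not passing. Adjusted over the list alone, 7 of these cell cycle genes rose. Of 7 cell cycle inhibitors Btg1 fell (log2 fold change -0.37), while adjusted over the list alone 1 rose and 3 fell, and the list was not called (camera adjusted p = 0.167). NOTCH pathway genes were lower as a list (13 tested, median -0.24, camera adjusted p = 0.004; adjusted p = 0.366 with an estimated correlation). The NOTCH target Hey1 fell from 137 ± 5.01 to 74.0 ± 5.94 CPM, Notch3, Dll1, Lfng and Nrarp also fell, and Jag1 rose (0.40), with 1 rise and 6 falls adjusted over the list alone. Ccne2 lost its call without any 1 control sample (edgeR, adjusted p from 0.0507 to 0.0589), Notch3 lost it without Cont_345 (0.0516), and Jag1, Lfng and Nrarp lost it in 7, 6 and 4 of the 8 fits with 1 sample left out.

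Genes shared by young neurons of any type were higher as a list (14 tested, median 0.27, camera adjusted p = 0.000214; adjusted p = 0.366 with an estimated correlation). Of these 7 rose and 7 did not pass, and adjusted over the list alone 8 rose. Of the 7, Stmn3 and Gap43 each lost their call in 7 of the 8 fits with 1 sample left out, and Snap25 in 6. Dcx, a microtubule protein of migrating neurons, went from 512 ± 26.4 to 708 ± 74.8 CPM (n = 4 each), and Syt1, Ina and Mapt rose by 0.44 to 0.69 on the log2 scale. Of 15 excitatory neuron genes Tbr1, a transcription factor of early deep layer neurons, rose from 229 ± 9.23 to 281 ± 18.5 CPM (edgeR, adjusted p = 0.00656) and Id2 rose 1.95-fold, while 12 did not pass. That list was not called (camera adjusted p = 0.292), with 2 rising and 4 falling adjusted over the list alone. Among 14 intermediate progenitor genes, Neurod4 (0.89) and Btg2 (0.23) rose, Dll1 fell (-0.42) and 11 did not pass, against 2 rising and 2 falling adjusted over the list alone (camera adjusted p = 0.801). Eomes, the marker of intermediate progenitors, had 285 ± 30.1 CPM in control and 313 ± 25.0 CPM in Sufu-cKO, a log2 fold change of 0.13 (SE 0.081; edgeR, adjusted p = 0.387). Btg2 kept its call only without Cont_345 or Mut_317 (otherwise adjusted p from 0.0531 to 0.0938 by edgeR).

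Among transcription factors of ventral telencephalic progenitors, Olig2 and Olig1 rose in all 4 Sufu-cKO samples. Olig2 (ENSMUSG00000039830, chromosome 16, 91225550 to 91228677) went from 2.26 ± 0.628 to 28.6 ± 11 CPM (12.6-fold, n = 4 each; edgeR, adjusted p = 0.000548), and Olig1 from 0.202 ± 0.063 to 1.90 ± 0.693 CPM. Gsx2, a determinant of lateral ganglionic eminence progenitors, had 1.33 ± 1.69 CPM in control and 12.3 ± 6.47 CPM in Sufu-cKO, and did not pass (log2 fold change 3.15, SE 0.929; edgeR, adjusted p = 0.0905). Dlx2, with 6.03 ± 6.55 and 23.8 ± 14.8 CPM, did not pass either (edgeR, adjusted p = 0.293). Of the 8 tested members 3 rose and 5 did not pass, while adjusted over the list alone 4 rose and 1 fell. Camera called the list higher (median 1.79, adjusted p = 0.00215), with adjusted p = 0.366 with an estimated correlation. Nkx2-1, a marker of the medial ganglionic eminence, was not tested. It had 96 counts in Cont_365, 0 to 5 in the other controls and 0 to 14 in the Sufu-cKO samples.

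GABAergic neuron genes varied widely between samples of 1 genotype. Gad1, the enzyme of GABA synthesis, had 5.77 ± 5.37 CPM in control and 11.5 ± 8.30 CPM in Sufu-cKO (n = 4 each; edgeR, adjusted p = 0.597). Of 16 tested members Npy rose (log2 fold change 1.69) and 14 did not pass, against 1 rise and 2 falls adjusted over the list alone (median 0.73, camera adjusted p = 0.603). The mean of the list lay between 0.79 and 2.76 log2 CPM in the controls and between 1.67 and 2.91 in the Sufu-cKO samples. Without Cont_370, which had the highest control value, Gsx2 was called (log2 fold change 4.58, edgeR adjusted p = 0.0138). In that fit Dlx2 (3.02, edgeR adjusted p = 0.114) and Gad1 (1.85, edgeR adjusted p = 0.253) also moved up but were not called. Gsx2 was not called in the other 7 fits with 1 sample left out.

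Choroid plexus genes fell together. Of the 10 tested members 6 fell, and adjusted over the list alone 9 did. Htr2c, a serotonin receptor of the plexus epithelium, went from 20.3 ± 3.15 to 5.98 ± 2.55 CPM (n = 4 each; edgeR, adjusted p = 0.0112), and Folr1, Calml4, Slc4a5, Sostdc1 and Kcne2 fell by 0.81 to 2.06 on the log2 scale. Ttr, the most abundant member, stood at -1.70 (SE 0.435) and was not called over all genes (edgeR, adjusted p = 0.0591). Camera called the list lower (median -1.28, adjusted p = 3.24e-06), with adjusted p = 0.366 with an estimated correlation. The mean of the list was lowest in Mut_340, at 1.91 log2 CPM against 3.25 to 3.38 in the other Sufu-cKO samples and 4.13 to 4.61 in the controls. Kcne2 kept its call only without Mut_340 (otherwise adjusted p from 0.0549 to 0.101 by edgeR), and Slc4a5 and Sostdc1 lost theirs in 4 of the 8 fits with 1 sample left out (up to 0.0882 and 0.100).

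Targets of canonical WNT signalling also fell. Lef1, a nuclear partner of beta-catenin, dropped from 61.1 ± 5.22 to 28.4 ± 4.07 CPM (n = 4 each; edgeR, adjusted p = 3.57e-05), and Rnf43, Tnfrsf19, Tcf7, Axin2, Nkd1 and Znrf3 fell by 0.28 to 1.13 on the log2 scale. These 7 of 12 tested targets also fell adjusted over the list alone, and 5 did not pass. Camera called the list lower (median -0.46, adjusted p = 1.18e-05), with adjusted p = 0.366 with an estimated correlation. Of 16 genes of the cortical hem, a source of WNT and BMP ligands at the dorsal midline, Wnt5a (-0.62) and Bmp7 (-0.49) fell and 14 did not pass, while 3 fell adjusted over the list alone. The hem list was not called (median -0.13, camera adjusted p = 0.0648), but passed as lower without Cont_294 (0.0179), Cont_345 (0.0459), Mut_317 (0.0297) or Mut_337 (0.00227). Bmp7 kept its call only without Mut_295, Mut_337 or Mut_340 (otherwise adjusted p from 0.0804 to 0.111 by edgeR), and Znrf3 lost it without Cont_345 (0.0676) or Mut_337 (0.0501).

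Genes graded along the axes of the cortical primordium changed in both directions. Nr2f1 went from 233 ± 29 to 371 ± 65.1 CPM (n = 4 each; edgeR, adjusted p = 0.00976), and Nr2f2 (log2 fold change 1.39) and Pax6 rose, while Emx2, Lhx2, Sp8 (-0.89) and Epha7 (-0.36) fell. Adjusted over the list alone 6 of 14 rose and 4 fell (camera adjusted p = 0.497). Among 12 Cajal-Retzius cell genes, Reln fell from 143 ± 12.7 to 108 ± 14.3 CPM, Ndnf rose 3.73-fold and 10 did not pass, against 2 rising and 2 falling adjusted over the list alone (camera adjusted p = 0.376). Reln lost its call without Cont_345 (edgeR, adjusted p = 0.0598), and Epha7, Sp8 and Nr2f2 lost theirs in 7, 5 and 4 of the 8 fits with 1 sample left out (adjusted p up to 0.115, 0.0661 and 0.0776).

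**Figure D3:**
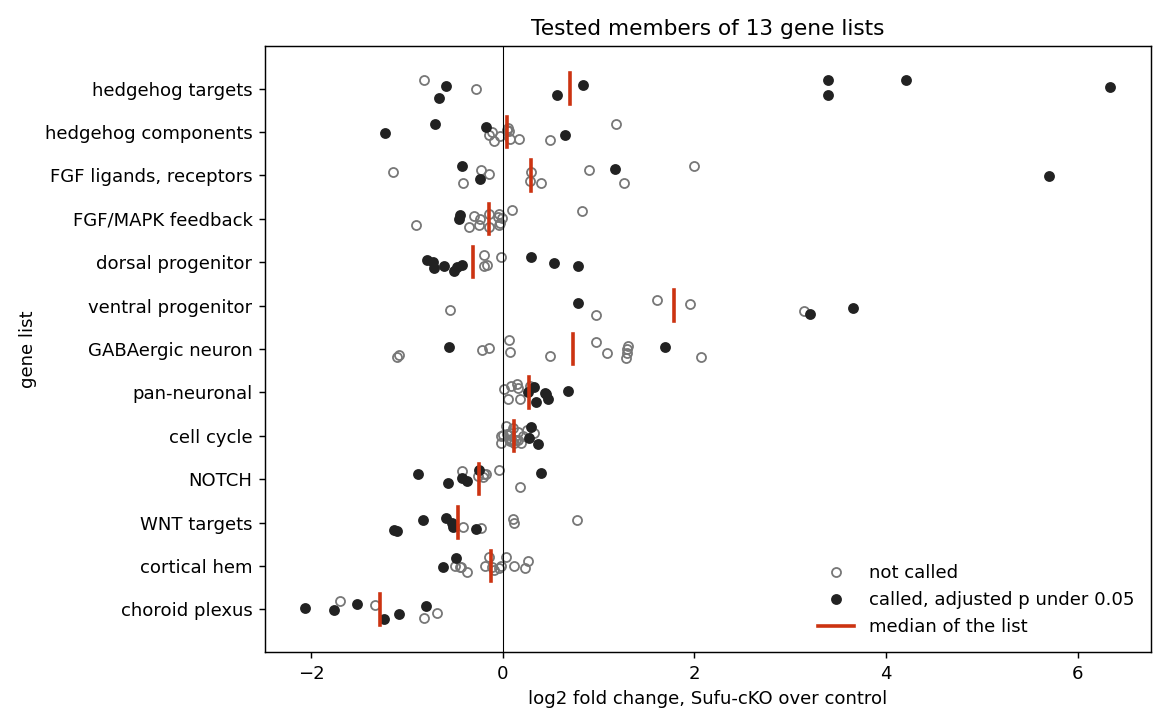
Log2 fold change (Sufu-cKO over control, n = 4 each) of every tested member of 13 gene lists fixed in advance, with filled points for genes called by edgeR and a line at the median of each list. The median is 1.79 for ventral progenitor genes, 0.71 for hedgehog targets, -0.46 for WNT targets and -1.28 for choroid plexus genes.

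Markers of other cell types were measured in the same libraries. Lists of endothelial (12 tested, median -0.28, camera adjusted p = 0.000281), pericyte (7 tested, -0.27, 0.00487), microglial (11 tested, -0.36, 0.000931) and erythroid genes (11 tested, -0.34, 0.00455) were lower in Sufu-cKO, each with adjusted p = 0.366 with an estimated correlation. The called members were Kdr, Cdh5 and Ramp2 for endothelium, Vtn and Notch3 for pericytes, and Pf4, Cx3cr1 and Csf1r for microglia, all lower, and adjusted over the list alone 7, 3 and 4 fell. For the erythroid list edgeR called 0 of 11 genes, with 4 at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by limma-voom, and 0 passed adjusted over the list alone. Of 12 mesenchyme genes Aldh1a2 rose (1.16) and Tbx18 fell (-0.54), also adjusted over the list alone, and the list was not called (median -0.07, mean 0.05, tested as lower, camera adjusted p = 0.274). The mean of that list was highest in Mut_337, at 5.79 log2 CPM against 4.57 to 5.08 in the other 7 samples, and without that sample the list passed as lower (adjusted p = 1.27e-06). Of these called members, Kdr, Vtn and Tbx18 kept their calls in all 8 fits with 1 sample left out, while Cdh5, Ramp2, Aldh1a2, Csf1r and Cx3cr1 each lost theirs in 6 and Pf4 in 5.

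Genes of neighbouring tissues gave a mixed picture. Of 6 tested diencephalic genes Olig3 (7.10-fold) and Tcf7l2 (1.89-fold) rose and Lhx9 fell (log2 fold change -0.56), while adjusted over the list alone 3 rose and 1 fell. That list was not called with all samples (median 0.81, camera adjusted p = 0.113) and passed as higher without Cont_294 (0.0219), Cont_345 (0.0337), Cont_365 (0.021) or Cont_370 (0.0191) or without Mut_317 (0.00437). Foxb1, which was not tested, had 25, 3, 30 and 17 counts in Mut_295, Mut_317, Mut_337 and Mut_340 and 0 to 1 in the controls. Of 7 surface epithelium genes Perp fell (-0.73, a call lost in 7 of the 8 fits with 1 sample left out), adjusted over the list alone 1 rose and 3 fell, and the list was not called (median -0.80, camera adjusted p = 0.0599). It passed as lower without Cont_294 (0.0395), Mut_337 (0.00503) or Mut_340 (0.0325). Krt5, a keratin of skin, had 102 counts in Mut_337, 23 in Mut_340 and 0 to 2 in the other samples. Without Mut_337 edgeR called 1423 genes, 614 higher and 809 lower.

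Genes that can respond to handling or RNA quality were also tested. Of 13 p53 targets Trp53inp1 fell (log2 fold change -0.25), also adjusted over the list alone (camera adjusted p = 0.16). Among 9 immediate early and heat shock genes Btg2 rose and Ier2 fell (-0.71), with 2 rising and 1 falling adjusted over the list alone (camera adjusted p = 0.959). For 12 hypoxia genes edgeR called 0, with 2 at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by limma-voom (camera adjusted p = 0.212). For 7 mitochondrial mRNAs edgeR, DESeq2 and limma-voom each called 0 and 0 had an unadjusted p under 0.05 (median -0.01, mean 0.03, camera adjusted p = 0.801). Adjusted over the list alone, 0 hypoxia genes and 0 mitochondrial mRNAs passed. The 4 tested sex-linked genes gave the same 0 calls by each tool, also adjusted over the list alone, and Xist had 3 to 20 counts per sample. Trp53inp1 lost its call without Cont_345 (edgeR, adjusted p = 0.072), Cont_365 (0.0588) or Mut_317 (0.0511). Over all 30 lists camera called 12, of which 4 were higher and 8 lower. With an estimated correlation 0 lists passed, 2 had an unadjusted p under 0.05, and fry called 13.

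Several of the largest changes lay outside the fixed lists. The homeobox genes Dbx1 and Dbx2, which mark intermediate domains of the neural tube, rose from 0.903 ± 0.431 to 34.3 ± 9.85 CPM and from 0.110 ± 0.098 to 5.20 ± 1.03 CPM (n = 4 each; edgeR, adjusted p = 2.12e-05 and 1.15e-05). Mobp, a myelin gene, Crh, a neuropeptide gene, and Pitpnm3 rose by 5.92, 5.31 and 4.26 on the log2 scale. Dio3, which encodes the enzyme that inactivates thyroid hormone, and its opposite-strand neighbour Dio3os rose by 6.31 and 6.02. Among falls, Dct, an enzyme of melanin synthesis, dropped from 40.9 ± 5.64 to 1.90 ± 0.477 CPM (21.6-fold lower; edgeR, adjusted p = 5.09e-08), and Bcan, a proteoglycan of the extracellular matrix, from 14.2 ± 4.84 to 0.938 ± 0.578 CPM. Mpped2 (408 ± 44.5 to 100.3 ± 23.2 CPM) and Ndrg2 (171 ± 32.3 to 41.6 ± 13.1 CPM) were the most abundant of the 10 largest falls, which also held Mybpc1, Rnd1, Nptx2, Msx3, Kcne2 and the neurotrophin receptor gene Ntrk3 (-2.01). Apart from Kcne2, these 20 genes kept their calls in each of the 8 fits with 1 sample left out. Their log2 fold changes moved to 6.82 for Mobp, 6.20 for Crh and 6.63 for Dio3os without Cont_365, and to 6.16 for Dbx2 without Cont_370.

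In the authors' deposited table, the number of genes with a false discovery rate under 0.05 was 1463, of which 679 were higher and 784 lower in Sufu-cKO. Of these, 1348 (92.1%) were also called by edgeR here, all with the same sign. Across the 15382 tested genes, which are not independent replicates, the log2 fold changes of the authors' deposited table and of the edgeR fit had a Pearson correlation of 0.9999 and a Spearman correlation of 0.9998. Both come from the same samples, and the deposited signal from the same counts, so the match checks samples and direction and is not independent evidence. The authors' deposited table gave log2 fold changes of -1.46 for Sufu, 4.22 for Gli1, 5.72 for Fgf15, 3.66 for Olig2 and -0.73 for Emx1.

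Called genes were also counted around the engineered loci, where DNA of another strain can flank an allele. Within 10 Mb of Emx1 (chromosome 6, 85187438 to 85204462) 20 of 131 tested genes were called (15.3%), against 10.9% elsewhere (odds ratio 1.47, 95% interval 0.86 to 2.38; 2-sided Fisher's exact test, p = 0.122). Within 10 Mb of Sufu 16 of 151 were called (odds ratio 0.96, 95% interval 0.532 to 1.62; 2-sided Fisher's exact test, p = 1).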

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

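The tests of ventral tissue and of choroid plexus cells in this part were chosen after the results they address were seen. In 11 of 218 groups of 4 samples (5.05%) 1 sample lay far from the other 3, where chance alone gives about 1 in 20, and 6 of the 11 were in Mut_340. In that sample Gli1 stood at 43.6 CPM (the other 3 Sufu-cKO samples 50.9 to 52.1), Kcne2 at 1.45 (8.21 to 8.8), Neurod4 at 23.7 (17.6 to 18.3) and Rnf43 at 2.26 (2.78 to 2.84). Cdkn1b stood there at 183 CPM (166 to 169) and mt-Co1 at 3860 (3060 to 3120). In Cont_370 Gsx2 was at 3.84 CPM (0.109 to 0.72 in the other controls) and Htr2c at 15.6 (21.4 to 22.3). Sox1 was at 103 CPM in Cont_345 (88.2 to 90.5), Npy at 2.39 in Mut_317 (1.36 to 1.39) and Hbb-y at 2750 in Mut_295 (2530 to 2550).

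Dlx1, Dlx2 and Gsx2 differed widely between samples of the same genotype, and Gsx2 was highest among controls in Cont_370. Ventral telencephalic tissue in some dissected pieces is a candidate explanation, since the mean of these 3 genes, chosen because they varied, followed that of GABAergic neuron genes (Dlx genes left out) within genotypes (r = 0.984, n = 8; permutation p = 0.00174, the smallest of 576 rearrangements, Benjamini-Hochberg adjusted p = 0.00347 over 2 relations). The correlation was 0.956 without the 2 farthest samples, but activation of ventral genes that varied between embryos would give the same relation, so both stay open. Loss of Sufu is argued against as the source of the spread among controls. There the mean of the 3 genes ran from -0.51 log2 CPM (Cont_345) to 3.74 (Cont_370), while Sufu stood at 124.57 and 104.73 CPM. As the whole cause of higher Olig2, such tissue is argued against, because with the GABAergic list mean as a covariate its log2 fold change was 3.167 (SE 0.32; edgeR, adjusted p = 0.000574) against 3.65 (SE 0.373) without. With that covariate Gsx2 (2.35, SE 0.256, adjusted p = 0.000301) and Dlx2 (0.914, SE 0.181, adjusted p = 0.0124) were also called by edgeR, while Dlx1 (0.456, SE 0.165, adjusted p = 0.161) was not. The covariate, unlike the correlation, kept Dlx5, Dlx6 and Dlx6os1, so for Dlx1 and Dlx2 it was not independent of related genes. Activation by loss of Sufu remains a hypothesis, found and tested on the same data.

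Choroid plexus genes were lowest in Mut_340 and lower in each Sufu-cKO sample than in each control by the list mean. Fewer choroid plexus cells in the pieces may account for this, as the within-genotype residuals of the 10 tested members had a mean correlation of 0.81, which shared regulation in the same cells would also give. A dorsal midline left out of the Sufu-cKO pieces would lower the cortical hem list too, and that list fell less than the choroid list. The hem list had a mean log2 fold change of -0.174 (SE over genes 0.069) against -1.299 (SE over genes 0.146) for the choroid list. This does not decide it, since whether hem genes were also expressed in other tissue of the pieces was not tested. The hem list mean among Sufu-cKO samples was highest in Mut_337 (4.66 log2 CPM), which also had the highest mesenchyme mean (5.79). Without Mut_337 the hem list passed as lower (camera adjusted p = 0.00227). In Mut_340 the hem list mean was the lowest, at 3.84 log2 CPM against 4.18 to 4.66 in the other Sufu-cKO samples and 4.30 to 4.67 in controls. A dissection that lost the plexus, alone or with the hem, and a smaller plexus in the mutant stay open, since genotype and dissection cannot be separated in these samples.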

How the results depend on the processing

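The covariates made from the GABAergic and choroid plexus lists were chosen after the data were seen. No paired analysis was possible because the groups share no replicate numbers. Against 1689 called genes, 3 other scalings called 1670 to 1693, with no low-count filter 1726, with the stricter filter 1603, DESeq2 2135, limma-voom 1681, edgeR without robust estimation 1675 and 1 surrogate variable 1591. No scaling moved the median of all genes by more than 0.019 on the log2 scale, and no named gene reversed under one. Against a 1.2-fold change edgeR called 716 genes (359 higher, 357 lower), a stricter question by construction. The GABAergic covariate left 929 calls (491 higher, 438 lower, with 907 of the 1689 kept), and the cause was not tested. The choroid covariate left 209 (133 higher, 76 lower, with 199 kept). Its list mean separated the genotypes, at 4.13 to 4.61 log2 CPM in controls and 1.91 to 3.38 in Sufu-cKO. It therefore takes up the genotype difference by construction, and the lost calls do not show that choroid content caused the changes.

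With 1 sample left out, the calls ranged from 1079 (without Cont_345) to 1836 (without Mut_295), with 537 to 939 higher and 542 to 897 lower. Fewer samples shift such counts by construction, but why these 2 samples gave the extremes was not tested. Sufu kept its direction and call throughout, at -1.513 to -1.404.

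Of the list results, camera with an estimated correlation called 0 of 30 lists, with 2 at an unadjusted p under 0.05. The preset correlation called 12 and fry 13. Hedgehog targets had an estimated correlation of -0.093, below the preset 0.01, so genes varying together are argued against as the cause for that list. The other called lists had 0.15 (cell cycle) to 0.81 (choroid plexus), and for them the cause was not tested. In the simulation with independent genes the camera adjusted p also rose, from 5.06e-18 to 0.00773. With an estimated correlation the adjusted p was 0.366 for hedgehog targets and for ventral progenitor genes and 0.378 for dorsal progenitor genes, which had 0.0551 by fry. With 1 sample left out the camera adjusted p of the FGF feedback list ran from 0.0339 to 0.586. Lists that reversed direction in some of these fits had adjusted p from 0.609 to 0.998 (hedgehog components), 0.454 to 0.997 (intermediate progenitors), 0.566 to 0.889 (immediate early and heat shock genes) and 0.288 to 0.888 (mitochondrial mRNAs).

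Genes that reversed with the choroid covariate had log2 fold changes of 0.086 (Kcne2), 0.104 (Bmp7), 0.17 (Slc4a5), 0.163 (Sostdc1), 0.209 (Cfap45), 0.245 (Ak7), -0.298 (mt-Co1) and -0.099 (Kdm5d). With the GABAergic covariate these were -0.143 (Gad1), -0.043 (mt-Co1) and 0.05 (Ddx3y). Kcne2, Slc4a5 and Sostdc1 belong to the choroid plexus list and Gad1 to the GABAergic list. Each of these genes was adjusted for a mean that contains it, which takes out its change in part by construction. With 1 surrogate variable mt-Co1 was at -0.014, and by limma-voom mt-Cytb was at 0.002. With 1 sample left out, values crossed 0 for Ldha (-0.026 to 0.095), mt-Co1 (-0.031 to 0.132), mt-Cytb (-0.081 to 0.102) and Ddx3y (-0.079 to 0.039). The cause was not tested for the other reversals. Fgf8, Shh and Nkx2-1 had too few reads to be tested at this depth, and low expression was not separated from depth.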

Other observations

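The tests of the Dlk1-Dio3 cluster in this part were chosen after the result was seen, and the 6 lists of imprinted, motile cilia, axon guidance and intermediate domain genes were written after the table of all genes was seen. Of the 35 splits of the 8 samples into 4 and 4, 1 gave as many called genes as the real split, namely the real split itself with 1689. The highest other split gave 4. The other splits mix the genotypes, so the difference between genotypes widens the spread within their groups and lowers their counts. With 35 splits the test can reach no smaller share than 1 in 35, so it does not by itself exclude chance.

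DNA of another strain beside the engineered alleles could add called genes near them. The odds ratio of a call within 10 Mb was 1.47 for Emx1 (2-sided Fisher's exact test, p = 0.122; 1.39 without Emx1 itself) and 0.96 for Sufu (p = 1 by the same exact test; 0.901 without Sufu itself). Neither test could tell, as the 95% intervals ran from 0.86 to 2.38 and from 0.532 to 1.62.

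Imprinted genes of the Dlk1-Dio3 cluster on chromosome 12 rose, 7 of 8 tested. Dlk1, a growth regulator expressed from the paternal chromosome, went from 8.57 ± 1.3 to 25.3 ± 5.24 CPM (2.94-fold, n = 4 each; edgeR, adjusted p = 5.53e-05), and the maternally expressed Meg3 rose 2.36-fold (edgeR, adjusted p = 0.0207), a call lost in 6 of the 8 fits with 1 sample left out (0.0508 to 0.0672). Rian lost its call without Cont_345 or Cont_365 (0.0572 and 0.0522) and Rtl1 without Cont_365 or Cont_370 (0.0588 and 0.0552), all by edgeR. A switch of imprinting between the parental chromosomes could raise one set only, and is argued against by a median log2 fold change of 1.285 for Meg3, Rian and Mirg beside 3.069 for Dlk1, Rtl1 and Dio3. The latter is the value of Rtl1, which ran from 2.394 (without Mut_337) to 3.95 (without Cont_294), while Meg3, Rian and Mirg stayed at 1.116 or above in each of these fits. A larger share of neurons or of mesenchyme is argued against as the whole cause. The mean log2 fold change was 0.279 (SE over genes 0.05) for pan-neuronal genes and 0.055 (SE over genes 0.14) for mesenchyme genes. Both lie far below the cluster median of 1.539. Regulation of the cluster in the Sufu-cKO cells stays open.

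Motile cilia genes fell, 21 of 55 tested, for example Dnah6 (3.35-fold lower; edgeR, adjusted p = 0.000592). Of the 21 calls, those of Ak7, Tekt4, Cfap45, Cfap54 and Cfap70 were lost in 6, 5, 4, 3 and 1 of the 8 fits with 1 sample left out (edgeR, adjusted p up to 0.0988). Loss of the choroid plexus cells that carry them may explain this, but the test could not tell. Within genotypes the list means had r = 0.93 (n = 8, permutation p = 0.238), and r was 0.636 without the 2 farthest samples.

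Other lists chosen that way are given as values. Because all these lists were chosen from the same data, their p-values below do not measure an error rate. Of 71 axon guidance genes 10 rose and 9 fell (26.8% called, against 11% of all tested genes), among them Plxnc1, a semaphorin receptor (6.47-fold; edgeR, adjusted p = 3.45e-08), and camera did not call the list (adjusted p = 0.906). With 1 sample left out, the call of Epha7 was lost in 7 of 8 fits, those of Ntng2, Efna4, Robo3 and Sema7a in 5 and that of Rgma in 4 (edgeR, adjusted p up to 0.133), while Plxnc1 kept its call. Of 14 genes of intermediate domains 8 rose and 2 fell, with Nkx2-3 going from 1.13 to 11.5 CPM (camera, adjusted p = 6.84e-05; adjusted p = 0.0574 with an estimated correlation). Of 36 imprinted genes outside the cluster 11 rose and 25 did not pass (camera, adjusted p = 0.000429; adjusted p = 0.0574 with an estimated correlation), and Peg10 rose 6.28-fold. In such fits 4 of the 11 outside the cluster lost their calls at least once (Impact in 7, Ppp1r9a and Usp29 in 6, Grb10 in 3; edgeR, adjusted p up to 0.131), as did Prdm8 (7) and Sp8 (5) among the intermediate domain genes (up to 0.106). All 43 imprinted genes together held 18 rises (camera, adjusted p = 1.63e-07; 0.0574 with an estimated correlation), the cluster had adjusted p = 1.24e-08 (0.0497), and the motile cilia genes 4.27e-12 (0.0574), all by camera.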
